A study of Mus musculus with 32 samples.

How the data were processed

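Gene expression was measured in the jaw primordia of mouse embryos at embryonic day 13.5 on 32 Affymetrix whole-genome mouse arrays. The mutants lacked Alk5 (gene symbol Tgfbr1), the type I receptor for TGF-beta ligands, in cells that had expressed the Wnt1-Cre transgene, which is active in the neural crest, and the controls were littermates. Each jaw, mandible or maxilla, was represented by its distal and its proximal end. Genotype, jaw and end made 8 groups of 4 arrays, numbered 1 to 4 in the labels. The labels do not say whether arrays with different numbers came from different embryos. Xist was high on the arrays of control number 2 (13.53 to 14.06) and mutant number 1 (13.34 to 13.90), with Y-linked genes low. All other numbers had Y-linked genes at 9.9 to 10.3. These 2 sets thus came from other embryos than the rest of their genotype, and control and mutant differed in sex within numbers 1 and 2. For the remaining numbers this is not known, so the p-values measure the spread between these arrays, part of which may be technical. Per the labels' protocols, RNA was extracted with a column kit, and labelled cRNA was made from 5 µg of total RNA.

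The deposited values are log2 expression values, 1 per probe set and array, made with RMA (background correction, quantile normalization and median polish summary) per the submitters' processing notes, with the version not stated there. Scanner files were not used here. RMA draws all arrays towards 1 distribution, so a shift of most genes in 1 direction would be removed, and probe sets of low signal have compressed differences. Array medians lay between 7.35 and 7.49 and array SDs between 2.37 and 2.56. The number of arrays limits the precision.

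Of 45101 probe sets, 34945 carried 1 gene symbol in the platform annotation, 932 carried several, 9160 carried none and 64 were manufacturer's controls. Of the single-symbol probe sets, 34741 were matched by Entrez identifier to a RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols. That table was used only for names and for which genes neighbour each other, since the files name no genome build, and no coordinates are given. A probe set was kept when it lay above its array's percentile 40 on at least 4 arrays, which left 29356. The probe set with the highest mean over all arrays then stood for its gene, which gave 13705 genes, of which 6533 had more than 1 probe set past the filter.

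Comparisons were made with limma 3.58.1 in R 4.3.3. A model of the 8 group means gave the genotype effect in each of the 4 regions, the differences between jaws and between ends in control tissue, and the interactions of genotype with jaw and with end, with 24 residual degrees of freedom. The average genotype effect was tested on the mean of the 4 regional arrays of each genotype and number, 4 against 4, with 6 residual degrees of freedom. P-values were moderated by eBayes and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Every adjusted p below comes from limma unless stated otherwise. The 36 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 36 lists of a comparison. Of 396 list tests, 106 passed with the preset correlation and 4 with an estimated one. The 4 were the lower-jaw identity list between jaws at both ends, the neuron markers between the ends of the control maxilla, and the inner ear and olfactory markers in the interaction of genotype with end.

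The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took Tgfbr1 first. For the average genotype effect it took the 12 largest changes in each direction among called genes with 1 sign in all 4 regions, for each regional genotype effect and each control difference the 8 largest in each direction, for each interaction the 4 largest in each direction, and for each described list up to 4 members with the smallest adjusted p and those chosen by other parts of the rule. Probe sets with several symbols or none named no gene.

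Arrays with equal numbers deviated together for the average genotype effect, where the correlations over genes of the control and mutant deviations from their group means were 0.44, 0.20, 0.40 and 0.23 for numbers 1 to 4. The numbers were therefore taken to pair the averaged values, on the evidence of the data and not of a label. A shift of number 1 alone, common to both genotypes, would also make these correlations positive for numbers 2 to 4. A pairing of numbers 2 to 4 was therefore not shown. In none of the other comparisons of 2 groups did every pair exceed 0.1. The 8 arrays of number 1 also stood apart in their spike-in controls. The Cre spike-in read 13.68 to 13.97 on those arrays and 12.42 to 13.23 on the other 24, so the handling of number 1 differed at the array step, and a difference in the tissue of number 1 may come on top. The planned models carried no batch term. The values without number 1, and with it as a covariate, stand beside the results they move. Number 1 holds 1 array per group and gives no test on its own, so the within-batch values are those of numbers 2 to 4.

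The procedure was tested on simulated data. Values for the 13705 genes were drawn around the real means with the real residual spread, with 200 genes changed by known folds and arrays drawn independently, so the averaged comparison lacks the correlation between arrays of 1 number. For the genotype effect in the distal mandible, 86.6% of genes changed 2-fold and 70.1% of those changed 1.5-fold were recovered. For the genotype effect in the proximal maxilla the shares were 89.6% and 64.2%, and for the compartment difference in the control maxilla 85.1% and 71.6%. Each gene was drawn with 1 spread pooled over the 8 groups. The real maxilla arrays had lower mean correlations with their group (0.945 to 0.979) than the mandible arrays (0.975 to 0.993), so the shares for the maxilla may be too high. For the average genotype effect over 4 regions they were 100.0% and 86.6%.

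Alternatives covered the low-signal filter, single probe sets, a fold minimum of 1.5, fixed and random replicate blocks, repeated quantile normalization, array weights, an embryo sex score as a covariate, fits restricted to the groups compared, an intensity trend with robust spread, and leaving out each number. After the data were examined, the batch of number 1 as a covariate and the removal of 2 arrays of doubtful quality, of 4 maxilla arrays, of each array and of each averaged value were added, with the list tests under each.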

Results

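The data comprised 32 arrays of mouse jaw tissue at embryonic day 13.5, with 4 arrays for each of the 8 combinations of genotype (control or neural crest deletion of Alk5), jaw (mandible or maxilla) and end (distal or proximal). Expression was on a log2 scale, so a difference of 1 corresponds to a 2-fold change. Arrays of 1 group correlated at 0.926 to 0.997 over the tested genes, and 0 pairs of arrays were identical. The first principal component, with 27.7% of the variance, separated mandible from maxilla, and the second, with 19%, separated the ends of the mandible. The distal and proximal arrays of the maxilla did not form separate groups on these components.

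**Figure D1:**
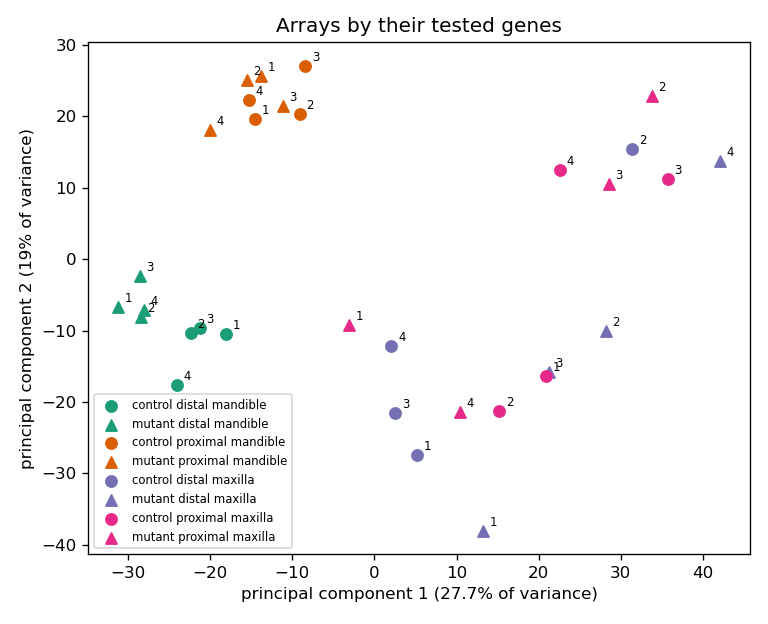
Each point is 1 of 32 arrays placed by its scores on the first (27.7% of variance, x axis) and second (19% of variance, y axis) principal component of the tested genes, with colour for region, circles for controls, triangles for mutants and the array number beside it. The 16 mandible arrays separate by end, while distal and proximal maxilla arrays are intermingled.

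The targeted gene was examined first. The tested probe set of Tgfbr1 did not fall in the mutants. It read 12.68 ± 0.07 (SD, n = 4) in control and 12.96 ± 0.03 in mutant distal mandible, and 12.71 ± 0.08 and 12.88 ± 0.07 in proximal mandible. The maxilla gave 12.65 ± 0.10 and 13.07 ± 0.18 at the distal end, and 12.71 ± 0.11 and 12.87 ± 0.05 at the proximal end. The rise of Tgfbr1 passed the test in the distal mandible (0.28 ± 0.07 SE, adjusted p = 0.0411) and the distal maxilla (0.42 ± 0.07, adjusted p = 0.00477), and not in the proximal mandible (adjusted p = 0.285) or proximal maxilla (adjusted p = 0.978). Expression arrays of this design probe the 3' end of transcripts, and where these probes lie relative to the deleted part was not determined, so this reading does not check the labels.

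The average genotype effect asked which genes changed in the mutant on the mean of the 4 regions. Lin28a, which encodes an RNA-binding protein that blocks let-7 maturation, was among the largest rises (1.32 ± 0.14 SE, adjusted p = 0.00672). Others were the ubiquitin ligase gene Trim71 (1.15 ± 0.13, adjusted p = 0.00781), the transcription factor gene Sall4 (1.54 ± 0.22, adjusted p = 0.0207) and the immunoglobulin superfamily gene Igdcc3 (1.93 ± 0.21, adjusted p = 0.00781). Ms4a7, expressed in macrophages, rose by 1.38 ± 0.15 (adjusted p = 0.00837). The arginase gene Arg1 rose by 1.63 ± 0.26 (adjusted p = 0.0273) and the lipid carrier gene Apoe by 0.98 ± 0.10 (adjusted p = 0.00672). Sned1, Fign, Eno3, Magel2 and Hsd11b2 completed the 12 largest rises, at 1.00 to 1.17. The largest falls were in the prostaglandin F receptor gene Ptgfr (-1.43 ± 0.24, adjusted p = 0.0349), the peptidase gene Enpep (-1.39 ± 0.27, adjusted p = 0.0497), Gprin3 (-1.35), Chodl (-1.31), the chemokine gene Cxcl5 (-1.29 ± 0.12, adjusted p = 0.00365) and Pantr1 (-1.27). Dclk3, Otor, Caln1, Lrrtm1, Egfl6 and the netrin receptor gene Unc5d fell by 1.06 to 1.18. With the number as a block, Ptgfr (adjusted p = 0.0692) and Caln1 (adjusted p = 0.053) did not pass. Lin28a lay under the level of the low-signal filter on all 16 control arrays, and Gprin3, Cxcl5 and Caln1 on all 16 mutant arrays, where differences are compressed, so the sizes for these 4 genes are approximate. In the brighter genotype, Lin28a lay under it on 10 of 16 mutant arrays, and Gprin3, Cxcl5 and Caln1 on 12, 10 and 7 of 16 control arrays. Most values of Lin28a, Gprin3 and Cxcl5 were thus near background in both genotypes.

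Among the fixed lists, extracellular matrix genes were lower in the mutants on average, with 3 of 31 measured members fallen, 0 risen and 28 not past the test, 16 fallen when adjusted over the list alone, and 10 fallen over all genes with the number as a block. Examples are Ogn (-0.99, adjusted p = 0.0164), the microfibril gene Mfap4 (-0.46, adjusted p = 0.025) and the proteoglycan gene Dcn (-0.98, adjusted p = 0.0421). The mean shift of this list was -0.384, and -0.253 without control number 1 (camera adjusted p = 2.78e-11, and adjusted p = 0.63 with an estimated correlation). Tendon genes had a mean shift of -0.709, with 1 of 11 fallen, 3 with the number as a block, and 5 adjusted over the list alone (camera adjusted p = 7.14e-06). Cartilage genes had a mean shift of -0.672, -0.426 without control number 1 and -0.325 without number 1, with 0 of 22 past the test over all genes and 9 lower adjusted over the list alone (camera adjusted p = 4.21e-07). Bone genes had a mean shift of -0.732, -0.375 without control number 1 and -0.409 without number 1, with 0 of 15 past the test, 1 lower with the number as a block and 2 lower adjusted over the list alone (camera adjusted p = 9.78e-06). Macrophage and leukocyte markers had 4 of 18 members risen, 3 with the number as a block, 0 fallen, and 11 higher adjusted over the list alone, including the complement genes C1qc (0.80, adjusted p = 0.0246) and C1qa (0.75, adjusted p = 0.0265), with a mean shift of 0.315, and 0.473 without number 1 (camera adjusted p = 4.21e-07). Their shift was -0.423 in the distal mandible and 0.496 to 0.647 in the other regions. Hypoxia and glycolysis genes had a mean shift of 0.178, and 0.268 without number 1, with a positive mean in each region. Skeletal muscle genes had regional means on both sides of 0, at 1.10 in the distal mandible, 0.547 in the proximal maxilla, -0.116 in the proximal mandible and -0.433 in the distal maxilla, so their average (0.274, 0.176 without mutant number 1 and 0.114 without number 1) does not describe every region. The proximal maxilla value rested on single arrays. It was 0.179 without mutant array 2 (camera adjusted p = 0.385) and 1.06 without mutant array 4, and 0.196, 0.021, 0.858 or 1.115 without number 1, 2, 3 or 4. Proliferation genes (0.092, and 0.049 without control number 1) had a mean of -0.028 in the distal maxilla. Brain and pituitary markers averaged 0.261, with -0.058 in the distal mandible, and did not pass without control number 4 (0.134, camera adjusted p = 0.36). BMP pathway genes (-0.166) did not pass with the number as a block (camera adjusted p = 0.0715). Each list called for this effect had an adjusted p of 0.63 with an estimated correlation, and fry called 0 of 36 lists. TGF-beta response genes had a mean shift of -0.157 with 1 of 23 fallen, 2 with the number as a block, and did not pass (camera adjusted p = 0.0597). By region the list passed in the proximal mandible and distal maxilla, and not in the distal mandible (-0.073) or proximal maxilla (-0.046).

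In all, 188 of 13705 genes passed for the average genotype effect, 69 higher and 119 lower. With the number as a block 388 passed, and 152 of the 188 were among them. Without number 1 the count was 939, and with number 1 as a batch covariate 1182, but without number 2, 3 or 4 it was 5, 14 or 1. Leaving out 1 averaged value moved the count to 85, 52 or 49 without control number 2, 3 or 4, and to 39, 30 or 35 without mutant number 2, 3 or 4.

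In the distal mandible, more genes were lower than higher in the mutant. The largest falls were in Pantr1 (-2.82 ± 0.40 SE, adjusted p = 0.000346), the neuronal growth gene Stmn2 (-2.49 ± 0.44, adjusted p = 0.00245), the homeobox gene Emx2 (-2.45 ± 0.29, adjusted p = 3.83e-05), the osteoclast-activating ligand gene Tnfsf11 (-2.42 ± 0.42, adjusted p = 0.00232). The glutamate receptor gene Grik3 (-2.31), Ptgfr (-2.28), the T-box gene Tbx18 (-2.21) and the keratocan gene Kera (-2.07) followed. Tnfsf11 and Grik3 lay under the filter level on all 4 mutant arrays, so their sizes are approximate. The largest rises were in Igdcc3 (1.82 ± 0.30, adjusted p = 0.00147), Fign (1.72 ± 0.25, adjusted p = 0.000346), Crym (1.71), Cited1 (1.69), Trim71 (1.54), Car14 (1.51), Dgkk (1.51) and Sned1 (1.49). Of 31 extracellular matrix genes 5 fell, 0 rose and 7 fell adjusted over the list alone. Among the 5 were the collagen cross-linking enzyme gene Lox (-1.97, adjusted p = 0.00314), Dcn (-1.53, adjusted p = 0.00893) and the hyaluronan synthase gene Has2 (-0.69, adjusted p = 0.00959). The list had a mean shift of -0.427, and -0.282 without control array 1 (camera adjusted p = 1.11e-06, and adjusted p = 0.63 with an estimated correlation). Macrophage and leukocyte markers were lower here, with 2 of 18 fallen, Pf4 (-1.18, adjusted p = 0.00246) and Ptprc (-1.08, adjusted p = 0.00853) (camera adjusted p = 0.00287, and adjusted p = 0.839 with an estimated correlation). This shift, -0.423, was -0.272 without control array 1 and -0.274 without number 1, and did not pass then (camera adjusted p = 0.0802 and 0.235). Skeletal muscle genes had a mean shift of 1.10 with 0 of 33 past the test (camera adjusted p = 3.22e-12, and adjusted p = 0.63 with an estimated correlation). In hypoxia and glycolysis 2 of 21 rose, Hk2 (0.50, adjusted p = 0.0334) and Ldha (0.30, adjusted p = 0.0428).

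The distal mandible count was 262 genes, 66 higher and 196 lower, and 351 without number 1, 88, 33 or 90 without number 2, 3 or 4, and 782 with number 1 as a batch covariate. With quantile normalization repeated, 42.4% of 236 calls were higher against 25.2%. Leaving out control array 1 or 3 gave 123 or 159 genes, and leaving out mutant array 1, 2, 3 or 4 gave 172, 128, 134 or 123. Control array 3 had a 3' minus 5' Gapdh signal of 2.23, against -0.18 to 0.12 on the other 31 arrays of the series.

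In the proximal mandible the mutant had higher Arg1 (3.55 ± 0.63 SE, adjusted p = 0.00293), Igdcc3 (2.36 ± 0.30, adjusted p = 8.57e-05), Lin28a (1.99 ± 0.26, adjusted p = 8.81e-05), and Ms4a7 (1.95 ± 0.29, adjusted p = 0.000374). Sall4 (1.95), the growth hormone-releasing hormone gene Ghrh (1.81), the homeobox gene Gbx2 (1.76) and Sned1 (1.74) were also among the largest rises. Lin28a read 5.05 in controls and 7.05 in mutants. Its 4 control arrays and 1 of its 4 mutant arrays lay under the filter level, so its size is approximate. The corticotropin-releasing hormone gene Crh fell most (-3.07 ± 0.54, adjusted p = 0.00264), followed by Ptgfr (-2.43 ± 0.44, adjusted p = 0.00295). Slc26a7 (-2.33), Cxcl5 (-2.08), Enpep (adjusted p = 0.0126), Prokr2 (-1.50), Gprin3 (-1.42) and the transcription factor gene Runx1 (-1.40 ± 0.22, adjusted p = 0.000915) fell as well. The 4 mutant arrays of Crh, Cxcl5 and Gprin3 lay under the filter level too, as did 3 of 4 control arrays of Gprin3 and 1 of 4 of Cxcl5. Of 31 extracellular matrix genes 5 fell, 0 rose and 13 fell adjusted over the list alone, including Has2 (-0.84), Ogn (-1.21) and the lumican gene Lum (-0.91) (camera adjusted p = 1.07e-15, and adjusted p = 0.172 with an estimated correlation). Bone genes had a mean shift of -1.03, and -0.471 without control array 1, with 0 of 15 past the test and 6 lower adjusted over the list alone (camera adjusted p = 1.71e-08, and adjusted p = 0.314 with an estimated correlation). Of 18 macrophage and leukocyte markers 2 rose, C1qc (1.26, adjusted p = 0.0137) and C1qa (1.10, adjusted p = 0.0227), and 10 were higher adjusted over the list alone (camera adjusted p = 5.84e-06, and adjusted p = 0.475 with an estimated correlation). TGF-beta response genes had a mean shift of -0.244, with 19 of 23 below 0 and 1 past the test, Lmcd1 (-0.99) (camera adjusted p = 0.000874, and adjusted p = 0.314 with an estimated correlation).

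The proximal mandible count was 172 genes, 81 higher and 91 lower, 198 without number 1, 64, 33 or 63 without number 2, 3 or 4, 486 with number 1 as a batch covariate and 366 without the 2 arrays of doubtful quality. It was 68 without control array 1 and 90 or 105 without mutant array 3 or 4.

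In the distal maxilla the mutant had higher Igdcc3 (1.93 ± 0.30 SE, adjusted p = 0.00307), the calretinin gene Calb2 (1.81 ± 0.30, adjusted p = 0.00307), and Lin28a (1.71 ± 0.26, adjusted p = 0.00307). The neutrophil granule gene Ngp (1.69), Ms4a7 (1.66), Hsd11b2 (1.48), Cpeb1 (1.44) and Nhlh1 (1.31) rose too. Chodl (-1.83 ± 0.36, adjusted p = 0.0133), Pde1a (-1.47 ± 0.26, adjusted p = 0.00593), the endothelial transcription factor gene Erg (-1.38), Caln1 (-1.26), Lrrn1 (-1.22), Lmcd1 (-1.22), Prr16 (-1.22) and Smoc2 (-1.20 ± 0.20, adjusted p = 0.00307) fell. The sizes are approximate for Lin28a and Cpeb1, whose 4 control arrays lay under the filter level, and for Caln1, whose 4 mutant arrays did. For Lin28a, 2 of the 4 mutant arrays lay under it as well. Of 31 extracellular matrix genes 4 fell and 0 rose. These were Col6a2 (-1.07), Ogn (-1.12), the collagen VI gene Col6a1 (-1.17) and Mfap4 (-0.42), and 13 fell adjusted over the list alone (camera adjusted p = 4.43e-10, and adjusted p = 0.302 with an estimated correlation). Of 18 macrophage and leukocyte markers 1 rose, Fcgr3 (1.02, adjusted p = 0.028), with a mean shift of 0.538, 0.845 without number 1 and 0.303 without number 4 (camera adjusted p = 2.29e-09, and adjusted p = 0.352 with an estimated correlation). TGF-beta response genes had a mean shift of -0.265, with 1 of 23 past the test, Lmcd1 (camera adjusted p = 0.0231, and adjusted p = 0.352 with an estimated correlation). This shift did not pass without number 2 or 3 (camera adjusted p = 0.117 and 0.0548), nor without control array 2 or mutant array 3. Neuron markers had a mean shift of 0.957 with 0 of 19 past the test (camera adjusted p = 3.16e-06, and adjusted p = 0.352 with an estimated correlation). In the other regions their mean was below 0, at -0.589 in the proximal mandible, -0.585 in the proximal maxilla and -0.44 in the distal mandible (camera adjusted p = 0.00576, 3.35e-05 and 0.282). The proximal mandible value was -1.019 without number 1. It was -0.318 and -0.423 without number 2 and 3, -0.427 and -0.226 without control array 2 and 3, and -0.332 without mutant array 4. The list did not pass in the latter settings. The proximal maxilla value was -1.215 without number 2, 0.075 without number 4 and -0.112 without control array 4, and did not pass without number 4 or that array.

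The distal maxilla count was 108 genes, 49 higher and 59 lower, 143 without number 1, 3 or 57 without number 3 or 4, 336 with number 1 as a batch covariate, 2 when only these groups were fitted, and 200 with 55.5% higher, against 45.4%, when quantile normalization was repeated. The count was 255 without the 4 maxilla arrays of control number 2 and mutant number 4, 22, 328, 25 or 36 without control array 1, 2, 3 or 4, and 40 or 62 without mutant array 2 or 3.

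In the proximal maxilla 9 genes passed. Those higher in the mutant were Ms4a7 (1.69 ± 0.29 SE, adjusted p = 0.0113), Igdcc3 (1.62 ± 0.30, adjusted p = 0.0286), Lin28a (1.32 ± 0.26, adjusted p = 0.042) and the muscle enolase gene Eno3 (1.13 ± 0.19, adjusted p = 0.0113). The 4 control arrays and 3 of the 4 mutant arrays of Lin28a lay under the filter level, so its size is approximate. Higher too were the macrophage genes Mpeg1 (1.02), C3ar1 (0.84) and Trem2 (0.64), and Nfya (0.45). The histone variant gene H2az2 was lower (-0.44 ± 0.07, adjusted p = 0.0113). Macrophage and leukocyte markers had a mean shift of 0.647, and 0.353 without number 2, with 0 of 18 past the test over all genes and 12 higher adjusted over the list alone (camera adjusted p = 4.39e-16, and adjusted p = 0.323 with an estimated correlation). Cartilage genes had a mean shift of -0.75, -0.435 without control array 1, -0.272 without number 1 and -1.16 without number 2, with 0 of 22 past the test (camera adjusted p = 3.89e-14, and adjusted p = 0.323 with an estimated correlation).

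The proximal maxilla count was 32 without number 1, 0, 2 or 18 without number 2, 3 or 4, 29 with number 1 as a batch covariate and 0 when only these groups were fitted. It was 28 without the 2 arrays of doubtful quality and 1 without the 4 maxilla arrays of control number 2 and mutant number 4. It was also 3 or 22 without control array 1 or 3, and 1 or 2 without mutant array 2 or 3.

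The regional genotype effects were compared by their calls, on arrays that no 2 regions shared, though with 1 estimate of the spread per gene common to all regions. The distal and proximal mandible had 18 genes higher in both, against 0.39 for independent lists, and 34 lower in both, against 1.3. The distal maxilla and proximal mandible had 10 higher in both, against 0.29, and 15 lower in both, against 0.392. Correlations of the fold changes, taken across genes, which are not independent replicates, ran from 0.201 between the maxilla ends to 0.537 between the proximal ends of both jaws. Arrays of 1 number may come from the same embryos, so part of these overlaps may come from embryos and not from genotype. Genes of small spread are also called more readily in every region, so overlaps above those of independent lists come in part from the common estimate. That estimate does not set the direction, and 1 gene was opposite in each of the 2 pairs of regions described.

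**Figure D2:**
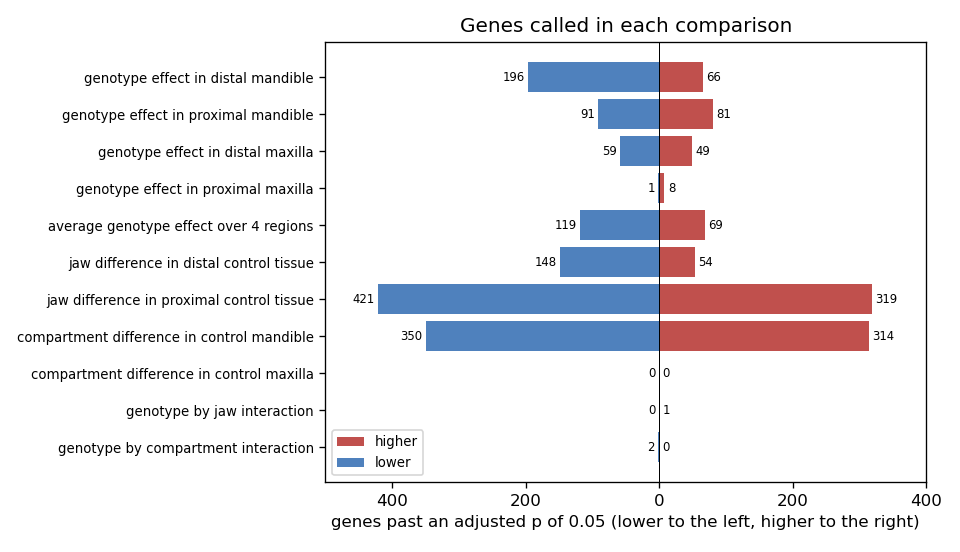
Bars give the number of genes past an adjusted p of 0.05 in each of the 11 comparisons, with lower genes to the left and higher genes to the right of 0 on the x axis. Of the genotype effects, the distal mandible had the most calls (66 higher and 196 lower) and the proximal maxilla the fewest (8 and 1).

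The interactions tested whether the genotype effect differed between jaws or ends. Trpm1, a cation channel gene known from pigment cells, differed between jaws, with the genotype effect higher by 1.26 ± 0.17 SE in the mandible (adjusted p = 0.00112). Trpm1 read 6.73 in control and 7.90 in mutant distal mandible, and 6.43 and 6.41 in distal maxilla. All 16 maxilla arrays of Trpm1 lay under the filter level, and of 2 other probe sets of Trpm1, 1 had the opposite sign. Emx2 (-2.07 ± 0.29, adjusted p = 0.00172) and E330013P04Rik (-1.32 ± 0.20, adjusted p = 0.0025) differed between ends on the mean of both jaws. Emx2 read 10.61 ± 0.14 (SD, n = 4) in control and 8.16 ± 0.23 in mutant distal mandible, and 9.82 ± 0.79 and 10.73 ± 0.36 in proximal mandible. These mandible values do not show whether the effect on Emx2 differed between the ends of the maxilla. Macrophage and leukocyte markers passed in both interactions with 0 of 18 members past the test. The mean was -0.556 for mandible minus maxilla (camera adjusted p = 1.43e-12, and adjusted p = 0.278 with an estimated correlation). It was -0.514 for distal minus proximal, -0.305 without number 2 and -0.807 without number 4 (camera adjusted p = 1.32e-08, and adjusted p = 0.684 with an estimated correlation). Only the distal mandible had a negative genotype effect for this list (-0.423, against 0.496, 0.538 and 0.647), so neither value describes a whole jaw or end.

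With limma, 1 gene passed for genotype by jaw and 2 for genotype by compartment. Without number 1 the counts were 19 and 0, and with number 1 as a batch covariate 6 and 2. Without number 2, 3 or 4 they were 0 each for jaw and 13, 0 and 11 for compartment.

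The jaw comparisons in control embryos asked which genes differed between mandible and maxilla at each end. At the distal end the mandible had higher Hand2, a transcription factor gene of the ventral pharyngeal arch (5.00 ± 0.53 SE, adjusted p = 2.36e-06). Other genes higher there were Cbln4 (3.84), the LIM homeobox gene Lhx9 (3.04), the Wnt antagonist gene Sfrp4 (2.76), the mandibular homeobox gene Pitx1 (2.71 ± 0.30, adjusted p = 4.63e-06), Tnfsf11 (2.08), Tbx4 (2.02) and Aqp4 (1.99). The maxilla had higher Otx2 (-4.85 ± 0.63, adjusted p = 2.86e-05), Lhx2 (-4.39 ± 0.52, adjusted p = 9.39e-06), where negative values are mandible below maxilla. Sp8 (-4.12), the neurogenic genes Neurod1 (-3.94) and Neurog1 (-3.57), the olfactory gene Fezf1 (-3.86), Six3os1 (-3.46) and Gata2 (-3.33) were also higher in the maxilla. The sizes are approximate for Lhx9, Tnfsf11 and Aqp4, which lay under the filter level on all 4 maxilla arrays, and for Otx2, Sp8, Neurod1, Neurog1, Fezf1 and Six3os1, which did on all 4 mandible arrays. Of 12 lower-jaw identity genes 4 were higher in the mandible, Hand2, Pitx1, Hand1 (0.88) and Gsc (0.99), and 0 lower, with 5 higher adjusted over the list alone, and this list held with an estimated correlation (adjusted p = 0.00367).

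At the proximal end the mandible was marked by muscle. Of 33 skeletal muscle genes 26 were higher and 1 lower than in the maxilla, with 30 higher adjusted over the list alone. Among the 26 were the synapse gene Rapsn (1.57), the acetylcholine receptor genes Chrna1 (2.26) and Chrng (1.75) and the fusion gene Mymk (2.07) (camera adjusted p = 7.85e-30, and adjusted p = 0.0708 with an estimated correlation). The largest differences upwards were Crh (4.61 ± 0.54 SE, adjusted p = 4.15e-06), Dlx1as (adjusted p = 0.00528), Mymx (3.77), Hoxa2 (3.51), Hand2 (3.47) and the contractile genes Tnnt2 (3.46), Myl1 (3.39) and Tnnc2 (3.35). Downwards they were the frontonasal homeobox gene Alx1 (-5.30 ± 0.47, adjusted p = 9.48e-08), Otx2 (-4.60), Nhlh2 (-4.22), Neurog1 (-4.01), Neurod1 (-3.99), Sp8 (-3.79), Insm1 (-3.65) and Lhx2 (-3.44). Crh and Hoxa2 lay under the filter level on all 4 maxilla arrays, and Otx2 and Sp8 on all 4 mandible arrays. The lower-jaw identity list had 7 of 12 members higher and 1 lower, with Pitx1 (2.56), Hand2, and Dlx4 (2.02) and Gbx2 (1.74), both under the filter level in the maxilla, among the 7, and held with an estimated correlation (adjusted p = 0.000206). Neuron markers had 7 of 19 lower and 0 higher (camera adjusted p = 1.45e-09, and adjusted p = 0.194 with an estimated correlation), and epithelium markers 6 of 25 lower and 0 higher (camera adjusted p = 1.22e-05, and adjusted p = 0.583 with an estimated correlation). The mean shift of the epithelium markers was -0.48, -0.283 without proximal maxilla array 1, -0.272 without number 1 and -0.737 without number 4, and that of the neuron markers -1.48, and -0.745 without number 4.

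The jaw comparisons called 202 genes at the distal end, 54 higher and 148 lower in the mandible, and 740 at the proximal end, 319 higher and 421 lower. Without number 1 the counts were 351 and 884, without number 2, 3 or 4 they were 66, 69 and 94 and 361, 267 and 567, with number 1 as a batch covariate 303 and 1025, and with only these groups fitted 115 and 412. When quantile normalization was repeated, 37.9% of the distal calls were higher against 26.7%, and without control distal mandible array 4 the distal count was 130.

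Within the control mandible, the distal end had higher Alx1 (5.48 ± 0.47 SE, adjusted p = 9.18e-08), the paired box gene Pax3 (3.64 ± 0.52, adjusted p = 0.000115), Hpse2 (2.98), Sfrp4 (2.92), Cbln4 (2.66), Hey2 (2.54), Dlg2 (2.53) and Lhx9 (2.37). The proximal end had higher Dlx1as (-4.67 ± 0.93, adjusted p = 0.00318), Crh (-3.73), Sim2 (-3.56), the neutrophil genes S100a9 (-3.49) and S100a8 (-3.31), the neurofilament genes Nefl (-3.46) and Nefm (-3.24), and Hoxa2 (-3.19). Hpse2 and Lhx9 lay under the filter level on all 4 proximal arrays, and Crh and Hoxa2 on all 4 distal arrays. Of 33 skeletal muscle genes 19 were lower distally and 1, Pax3, was higher (camera adjusted p = 9.29e-24, and adjusted p = 0.152 with an estimated correlation). Of 10 distal jaw identity genes 4 were higher and 0 lower, Alx1, Bmp4 (1.42), Hand2 (2.09) and Hand1 (0.77) (camera adjusted p = 3.82e-07, and adjusted p = 0.149 with an estimated correlation). Of 25 epithelium markers 6 were higher and 0 lower, including Esrp1 (1.09) and the E-cadherin gene Cdh1 (0.90) (camera adjusted p = 2.93e-08, and adjusted p = 0.336 with an estimated correlation). In all 664 genes passed, 314 higher and 350 lower, 937 without number 1, 400, 96 or 260 without number 2, 3 or 4, and 925 with number 1 as a batch covariate. The count was 342 without proximal mandible array 3 and 366 without distal mandible array 4.

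Between the ends of the control maxilla 0 genes passed with limma, and 405 had an unadjusted p under 0.05. The count was also 0 without number 1 and with number 1 as a batch covariate, 153 with array weights, and 184 without the 4 maxilla arrays of control number 2 and mutant number 4, a choice made after the data were examined. It was 8 without number 2, 4 without distal maxilla array 2 and 1 without proximal maxilla array 2. Neuron markers were lower distally with a mean difference of -1.30 and 0 of 19 past the test, a shift that passed with an estimated correlation (adjusted p = 0.0479). It was -0.826 without proximal maxilla array 4, and leaving out any 1 of 7 of the 8 arrays ended that call (adjusted p up to 0.239). Dcx differed by -1.55, Elavl4 by -1.57 and the peripherin gene Prph by -2.42, each with an adjusted p of 1.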

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

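The tests of the maxilla pattern below were chosen only after the result was seen, while the counts of other splits of the arrays were planned.

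The maxilla arrays did not separate by end. For each genotype and number, the proximal minus distal difference over all tested genes was projected on the mean difference of the other pairs, so that 1 means the same direction and size. In the maxilla this mean left out control number 2 and mutant number 4. These 2 pairs gave -1.195 and -1.378, while the other 6 pairs gave 0.267 to 1.106. The 8 mandible pairs, each projected on the mean of all other mandible pairs, gave 0.643 to 1.105. With all other maxilla pairs in the mean, the 2 maxilla pairs gave -1.596 and -1.81 and the other 6 gave 0.285 to 1.012. A boundary between the 2 pieces that varied between embryos would leave no projection below 0 if the ends of both jaws differed in the same genes. On the mean difference of the mandible, for which no maxilla pair had to be picked, both pairs gave -0.663 and the other 6 gave 0.207 to 0.694. Whether the mandible difference is a fit reference for the maxilla was not tested, and this reference was chosen with the maxilla values known. A varying boundary therefore stays open. Crossed distal and proximal labels within both pairs (the higher value, -1.195) stay open, since the pairs were picked for the sign of these values, and the labels were used as given. In 3' to 5' Gapdh difference, signal SD or array weight, 1 of the 4 arrays lay outside the range of the other 12 maxilla arrays. This was mutant distal maxilla 4 with an SD of 2.555, where the highest other was 2.55, a gap too small to show poor quality. The other 12 include mutant distal maxilla 1 (SD 2.373, array weight 0.071), so a poor array could hardly fall below their range. Array quality therefore stays open, and no biological explanation was tested.

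Among the array measures, 11 of 40 groups of 4 held a value far from the other 3, where chance gives about 1 in 20 (5%). Control distal mandible 3 had a 3' minus 5' signal of 2.233 for Gapdh and 1.84 for actin and an 18S rRNA signal of 12.608. Mutant distal mandible 1 had an actin 3' minus 5' signal of 0.254, an 18S rRNA signal of 14.194 and a mean correlation with its group of 0.987. Mean correlations were 0.975 for control proximal mandible 1 and 0.985 for mutant proximal mandible 1. The 18S rRNA signal was 14.443 on mutant proximal mandible 4 and 13.287 on mutant proximal maxilla 4, and the signal SD was 2.373 on mutant distal maxilla 1.

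Among named genes, 16 of 249 groups of 4 held such a value, near the share that chance gives (5%). Control number 1 stood apart in Cited1 (8.135, distal mandible), Slc26a7 (10.054, proximal mandible), Sfrp4 (11.88 in distal and 8.004 in proximal mandible), Pitx1 (8.452, distal maxilla), Hoxa2 (4.953, proximal mandible) and the averaged Ptgfr (8.894). Control proximal maxilla 4 was low in Otx2 (5.737), Sp8 (5.402) and Lhx2 (7.903), and control proximal maxilla 2 in C3ar1 (7.267). In the mutants these values were Ms4a7 at 9.653 in proximal mandible 3, Ngp at 8.739 in distal maxilla 1, Mpeg1 at 9.108 in proximal maxilla 2, and the averaged Sall4 at 8.994 for number 1 and Sned1 at 9.742 for number 3.

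The genotype effect differed between jaws for Trpm1 by 1.262, and between ends for Emx2 by -2.074 and for E330013P04Rik by -1.316. The inner ear and olfactory markers differed between ends with a mean of 0.505, which held with an estimated correlation (camera adjusted p = 0.0378), with 0 of 8 members past the test. Leaving out any 1 of 16 of the 32 arrays ended that call (adjusted p from 0.00317 to 0.346 over all of them), and without number 1 the list did not pass with the preset correlation (adjusted p = 0.0544).

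Other splits of the same arrays were counted, the real split included. Only the real split gave as many genes for the genotype effect in the distal mandible (1 of 35 splits, 262 against 1 in the highest other) and the proximal mandible (1 of 35, 172 against 2). The average genotype effect was fitted without pairing, but its values were taken to pair by number. Only 8 splits part all 4 numbers, too few for a share under 5%. The real split gave 188 and the highest other of these 0, and over all 35 splits without pairing the highest other was 3. As the pairing is uncertain, chance is left open there. Only the real split also gave as many genes for the jaw difference at the distal end (1 of 35, 202 against 116) and the proximal end (1 of 35, 740 against 74). So it was for the ends of the control mandible (1 of 35, 664 against 10). A share of 1 of 35 is the lowest that 35 splits can give. The 11 comparisons were counted without adjustment, and these splits took no account of the numbers. Chance is thus less likely for these comparisons but not excluded. Other splits gave as many genes for the genotype effect in the distal maxilla (3 of 35, 108 against 792) and the proximal maxilla (3 of 35, 9 against 453), and for the ends of the control maxilla (35 of 35, 0 against 172), so chance is not excluded there. It is not excluded for genotype by jaw (5 of 100 drawn splits, 1 against 254) or genotype by compartment (5 of 100 drawn splits, 2 against 22). The drawn splits of the interactions exchanged arrays between jaws or between ends. Jaw or end differences can therefore enter these counts, which decide nothing about chance. For the genotype effects in the maxilla, splits with several times the real count point to a structure of the maxilla arrays other than genotype.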

How the results depend on the processing

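The batch covariate, the removal of doubtful, single or averaged arrays and the list tests under those settings were chosen after the data were examined, the other alternatives before. Among 1756 values of 137 named genes under settings that kept all numbers, 1651 kept their direction and side of the threshold, 97 lost the call, 8 gained it and 0 reversed. Leaving out a number gave 548 such values, of which 205 lost the call and 0 reversed. Of the list shifts, 148 of 636 values under settings and 86 of 424 without a number lost the call, and 4 of the latter reversed. Without single or averaged arrays, 144 of 1160 list values lost the call, 2 reversed in camera, and 8 means changed sign. Cartilage genes between the maxilla ends ranged from -0.468 to 0.124. The shift of skeletal muscle in genotype by compartment was -0.245 without number 3 and ranged from -0.362 to 0.814 over all that was left out. Neuron markers in the proximal maxilla ranged from -1.215 to 0.075, and Schwann and glial markers between the maxilla ends from -0.562 to 0.077, each positive without number 4. An estimated correlation left 4 of 106 list calls. Most counts of calls moved with the setting, and except where fewer arrays or a stricter threshold was the alternative itself, the cause was not tested.

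The values that follow are counts of called genes. Dropping the filter gave 1 (maxilla ends) and 2 (genotype by jaw). A stricter filter gave 0 (genotype by jaw). Testing every probe set gave 110 (average effect), 304 (distal jaw difference), 1 (maxilla ends) and 6 (genotype by compartment). A 1.5-fold minimum gave 157 (distal mandible), 71 (distal maxilla) and 86 (average effect). The fixed replicate block gave 729 (distal mandible), 478 (proximal mandible), 315 (distal maxilla), 34 (proximal maxilla), 388 (average effect, 152 of the 188 among them) and 4 (genotype by jaw). A random replicate block gave 325 (distal jaw difference), 12 (genotype by jaw) and 5 (genotype by compartment). Repeated quantile normalization gave 200 (distal maxilla), 30 (proximal maxilla) and 5 (genotype by jaw). Array weights gave 2641 (distal mandible), 3368 (proximal mandible), 2480 (distal maxilla), 213 (proximal maxilla), 1687 (average effect), 1197 (distal jaw difference), 2625 (proximal jaw difference), 4445 (mandible ends), 153 (maxilla ends), 878 (genotype by jaw) and 579 (genotype by compartment). Fitting only the groups compared gave 2 (distal maxilla), 0 (proximal maxilla), 115 (distal jaw difference) and 412 (proximal jaw difference). Treating all 32 arrays as separate samples gave 1634 (average effect). All 32 arrays with a random replicate block gave 562 (average effect). The batch covariate gave 782 (distal mandible), 486 (proximal mandible), 336 (distal maxilla), 29 (proximal maxilla), 1182 (average effect) and 6 (genotype by jaw). Removing the 2 arrays of doubtful quality gave 366 (proximal mandible), 28 (proximal maxilla) and 2 (genotype by jaw). Removing the 4 doubtful maxilla arrays gave 255 (distal maxilla), 1 (proximal maxilla), 96 (average effect), 184 (maxilla ends) and 26 (genotype by compartment). Leaving out each number in turn gave 33 to 351 (distal mandible), 33 to 198 (proximal mandible), 3 to 143 (distal maxilla), 0 to 32 (proximal maxilla), 1 to 939 (average effect), 66 to 351 (distal jaw difference), 267 to 884 (proximal jaw difference), 96 to 937 (mandible ends), 0 to 8 (maxilla ends), 0 to 19 (genotype by jaw) and 0 to 13 (genotype by compartment). Leaving out control distal maxilla array 2 alone gave 328 (distal maxilla). Outside the average effect, equal numbers did not deviate together in every pair, with correlations down to -0.475 in the proximal maxilla. Of the 8 arrays of a comparison, 2 to 6 correlated best with their own number, so there the block results say only how the counts move. For the average effect a shift of number 1 alone could give the pairing, so the same limit may apply. The embryo sex score and the intensity trend moved no count by over 1.5 times. Restricting the fit to the groups compared was not run for the interactions, which use all groups. Probe sets near background limit what low genes can show.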

Other observations

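The tests in this part were all chosen after the result was seen, and the list of early embryonic genes was written then too.

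Of 14 genes listed for early embryonic expression or a link to Lin28 and let-7, 12 were measured. In the average genotype effect 7 rose, 5 did not pass and 0 fell. Beside the 4 leading genes, Prtg rose by 0.68 (adjusted p = 0.0349), Arid3a by 0.31 (adjusted p = 0.0413) and Nr6a1 by 0.27 (adjusted p = 0.0408). Arid3b (0.46, adjusted p = 0.0737), Igf2bp1 (0.33, adjusted p = 0.081), Igf2bp3 (0.19), Dnmt3b (0.22) and Hmga2 (0.01) did not pass. With the number as a block 5 rose, without Prtg (adjusted p = 0.0631) and Nr6a1 (adjusted p = 0.0518). The list was written around genes already seen to rise, so its count is not independent evidence. In the distal mandible Lin28a read 5.02 in controls and 5.30 in mutants, and in the proximal mandible 5.05 and 7.05. The low-signal filter lay at 6.66 to 6.86, so most of these values are near background.

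Igdcc3, Lin28a, Trim71 and Sall4 were higher and matrix and skeletal lists lower, which younger mutant embryos or an older control number 1 could give. Without control number 1 the mean difference of the 4 genes was 1.358. These genes were chosen as called rises in the same values, so this could hardly come out otherwise and decides nothing for them. The shifts of bone and extracellular matrix genes were -0.375 and -0.253 without control number 1, and -0.409 and -0.273 without number 1. This argues against an older control number 1 as the whole source of these 2 shifts. The cartilage shift moved from -0.672 to -0.426 without control number 1 and 1 mutant value overlapped the other controls, so for cartilage this stays open. Blood was used as a clock outside the neural crest, since embryonic Hbb-bh1 falls with age, and the signal of a probe set carrying several adult beta-globin symbols minus that of Hbb-bh1 was 2.737 in control and 3.285 in mutant number 1 and 1.153 to 2.176 in the others, so number 1 read later in both genotypes. Within numbers it was higher in the mutant in 4 of 4 (1.68 in controls and 2.29 in mutants, with a mean paired difference of 0.607 and an SD of 0.061, and a two-sided exact permutation p of 0.257 without pairing), the opposite of what younger mutants would show, on 1 clock only and by a paired rule, where an unpaired rule that was also tried would leave younger mutants open. A change that depends on Tgfbr1 in crest-derived tissue stays open as a hypothesis: the mean of the 4 leading genes was higher in 16 of 16 pairs of region and number, but the genes were chosen for rising in every region, so that count decides nothing.

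H2az2 was lower in the mutant in all 4 regions, and its tested probe set parted the genotypes completely, with 16 control arrays at 13.46 to 13.88 and 16 mutant arrays at 13.18 to 13.45. As background, a widely used Wnt1-Cre transgene is known to be inserted at H2az2, and this insertion is a candidate explanation. It was required that both probe sets part the genotypes, and the second did not: 7 of 16 mutant arrays lay above its lowest control array, although its mean difference was -0.677, so the requirement failed for 1 of the 2 probe sets. Cre and the deletion come together in this design, so the insertion cannot be told apart from a response to the loss of Tgfbr1. Without number 1 the difference was -0.472. The tested probe set had parted all arrays of both genotypes, and number 1 holds 1 array per group. This value could therefore hardly come out otherwise and decides nothing about the batch of number 1. A wider passenger region stays open, since 3 of the 50 tested genes nearest to H2az2 had an unadjusted p under 0.05, where 7.02 were expected, and the exact 95% interval reaches 16.5%.

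Xist read 9.69 and 10.72 on the distal and proximal maxilla arrays of control number 3, between the levels of the other arrays, while Y-linked genes averaged 10.05 and 9.97 there. The distal and proximal mandible arrays of control number 3 read 6.70 and 6.84 for Xist, so its maxilla and mandible arrays differed. The average genotype effect takes them as 1 unit. Whether the 2 maxilla arrays hold tissue of 2 embryos was not tested. Without the distal maxilla array of control number 3 the distal maxilla count was 25, and without the proximal one the proximal maxilla count was 22.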
